A study of Mus musculus and Danio rerio with 18 samples.

How the data were processed

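The libraries came from freshly isolated mouse muscle stem cells treated in medium with horse serum and bFGF, and from zebrafish blastomere-derived myogenic progenitor cells treated in medium without serum and bFGF. Per the labels' protocols, RNA was purified with a micro-scale column kit, amplified with the SMART-Seq v4 kit for very small amounts of RNA and made into libraries by tagmentation, which does not keep the strand. The deposited values are FPKM, by definition fragments scaled by gene length and by the mapped fragments of the library. There was 1 column per library and 1 table per species. Per the submitters' processing notes, the tools were cutadapt, TopHat2 2.0.11 and Cufflinks 2.2.1 and the genome builds GRCm38 for mouse and GRCz11 for zebrafish. The annotation release, the strand setting and the scaling between libraries are not given in the sources used here. Deposited names point to Cuffnorm for the mouse values and Cuffdiff for the zebrafish values, so the scaling may differ between the species. Each column was assigned to its sample by the name it shares with the sample's labels. Nothing in the labels says whether replicates came from separate animals, clutches or cultures, so p-values measure the spread between these samples, which may be technical.

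FPKM are not counts, and the depth of each library is unknown. Among genes seen in few libraries, the FPKM worth of 1 fragment was taken relative to DMSO replicate 1. It lay between 0.798 and 1.20 in mouse and between 0.816 and 1.33, with less sharp values, in zebrafish, so relative depths differed modestly. In mouse it was 1.17, 1.06 and 1.20 with LPA, 1, 0.946 and 0.946 with DMSO and 0.877, 0.986 and 0.798 with NFA. A higher value points to a shallower library. Every mouse LPA library was thus shallower than all other mouse libraries, so depth and LPA treatment cannot be separated there. No 2 libraries held identical values. Because a gene's FPKM divides by its length, genes shorter than a sequenced fragment have unstable values. Because unstranded reads cannot be assigned to a strand, overlapping antisense genes are uncertain. Near-identical paralogs and pseudogenes are uncertain too, since their reads are hard to tell apart. An exact 0 may be a failed estimate.

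From these values log2(FPKM + 1) was computed for genes with FPKM of at least 1 in at least 3 libraries, and each species was fitted on its own with limma 3.58.1 in R 4.3.3, all 9 libraries in 1 model of 3 groups with the variance trend, without a block. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. There were 39 gene lists of pathways, markers of other cell types and signs of RNA quality. They were written before the data were examined, as were the tests between groups and most alternatives, but not all tests of explanations. Of 788 mouse entries 781 were found, and of 994 zebrafish entries 955. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists, with an estimated correlation and fry as alternatives. Fry tests whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. Figures were drawn with matplotlib.

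Named genes followed a rule. For each compound against DMSO these were up to 10 genes per direction with the largest change among those past the threshold whose groups did not overlap, and up to 5 per direction for LPA against NFA. Where fewer than 3 passed, the 3 with the smallest p were added as not passing. Up to 4 members with the smallest p were taken from each list described, and the Lpar and Ptgs genes were always given. Clone names, Gm, Rik, si: and zgc: models were passed over but counted. Genes named outside the rule are said to be so. Mouse gene IDs were matched to GENCODE M21, which uses the same build, and 37691 of 39171 matched. No zebrafish annotation was used here, so zebrafish genes carry the names paired with IDs in the deposited table and no coordinates.

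The script was tested on simulated data drawn from the real means and spreads, with 100 genes changed by 1 and 100 by 2 on the log2 scale between LPA and DMSO, taken from genes that were not near the filter. In mouse, over 24213 genes, it recovered 4% of genes changed by 1 and 76% of those changed by 2, with 4 false calls. In zebrafish, over 15928 genes, it recovered 89% and 99%, with 18 false calls. The simulated genes were independent, with no batch or component shared by genes. Many genes were also changed at once, which eases the adjusted threshold. Recovery in the real libraries may therefore be lower. Chance correlations from shared DMSO libraries were taken from 100 simulations of unchanged groups. Zebrafish and mouse genes were matched when the zebrafish symbol equalled the mouse symbol in lower case, with or without a final a or b. Alternatives were another pseudocount (0.1), no filter, a filter of 5 FPKM, other scalings, fewer libraries, a replicate block, no trend and array weights.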

Results

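RNA was sequenced from freshly isolated mouse muscle stem cells and from zebrafish myogenic progenitor cells grown from blastomeres, each treated with DMSO as the control, LPA at 5 uM or NFA at 10 uM for 2 h. There were 3 replicates in each of 3 groups per species, 18 libraries in all. The 2 compounds were used at different doses, so the comparison between them is one of these treatments, not of equal doses. The mouse table held 39171 genes, of which 24213 reached an FPKM of 1 in at least 3 of the 9 libraries, and the zebrafish table held 32519 genes, of which 15928 did. The mouse libraries had between 27161 and 29773 genes above 0 and the zebrafish libraries between 26660 and 27792. In mouse, between 1089 and 1387 of 1817 olfactory, vomeronasal and taste receptor genes were above 0. These receptor genes were kept as a measure of background, so a mouse gene above 0 need not be expressed in muscle stem cells. The same caution applies to Vmn1r12 and the Olfr genes named below. Gm10800 and the models grouped with it held between 8.11% and 15.95% of all FPKM in the mouse libraries. Replicates resembled each other less in mouse, where the correlation of log2 values within a group lay between 0.853 and 0.891, than in zebrafish, where it lay between 0.972 and 0.982. Libraries of different groups were about as alike, at 0.845 to 0.902 in mouse (median 0.865, against 0.868 within groups) and 0.968 to 0.983 in zebrafish (median 0.978 for both). These are correlations across genes, which are not independent replicates. The median standard error of a log2 fold change was accordingly 0.388 in mouse and 0.168 in zebrafish. Fold changes are given as log2 differences of FPKM + 1 with their standard error, which understates the change of low genes, and FPKM values as mean ± SD with n = 3. Counts at an unadjusted p under 0.05 are set against the 5% of tested genes expected with no change: for LPA, NFA and LPA against NFA they were 4.06%, 6.63% and 6.43% in mouse and 8.43%, 2.74% and 6.99% in zebrafish.

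In the zebrafish progenitor cultures, LPA lowered a set of genes that included tp63, which encodes a transcription factor of basal epidermis, cdh1, which encodes E-cadherin, and cldnc, which encodes a claudin of tight junctions. FPKM of tp63 (ENSDARG00000044356) was 19.4 ± 3.98 with DMSO and 7.27 ± 1.43 with LPA, a log2 fold change of -1.29 ± 0.18 (limma adjusted p = 0.0237). FPKM of cdh1 was 60.4 ± 5.77 with DMSO and 35.1 ± 1.27 with LPA, a log2 fold change of -0.77 ± 0.11 (limma adjusted p = 0.0263). FPKM of cldnc (ENSDARG00000015955) was 26 ± 4.21 with DMSO and 8.41 ± 1.86 with LPA, a log2 fold change of -1.53 ± 0.17 (limma adjusted p = 0.0113). Of the 12 measured epidermal and epithelial cell markers, all 12 were lower with LPA, 2 passed the test over all genes and 10 passed when adjusted over the list alone. Their median log2 fold change was -0.70, and the list as a whole was lower than other genes (camera adjusted p = 1.87e-14; adjusted p = 0.0235 with an estimated correlation). With an estimated correlation the adjusted p lay between 0.0205 and 0.145 over 13 alternatives and was under 0.05 in 7 of them; it was 0.05 or higher with libraries scaled to the same median and without DMSO replicate 2, any 1 of the LPA replicates or NFA replicate 2. Other members were epcam, an epithelial adhesion gene, at -0.64 ± 0.12, and the keratin gene cyt1 at -0.91 ± 0.18, which did not pass over all genes (limma adjusted p = 0.0582 and 0.0820).

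**Figure D1:**
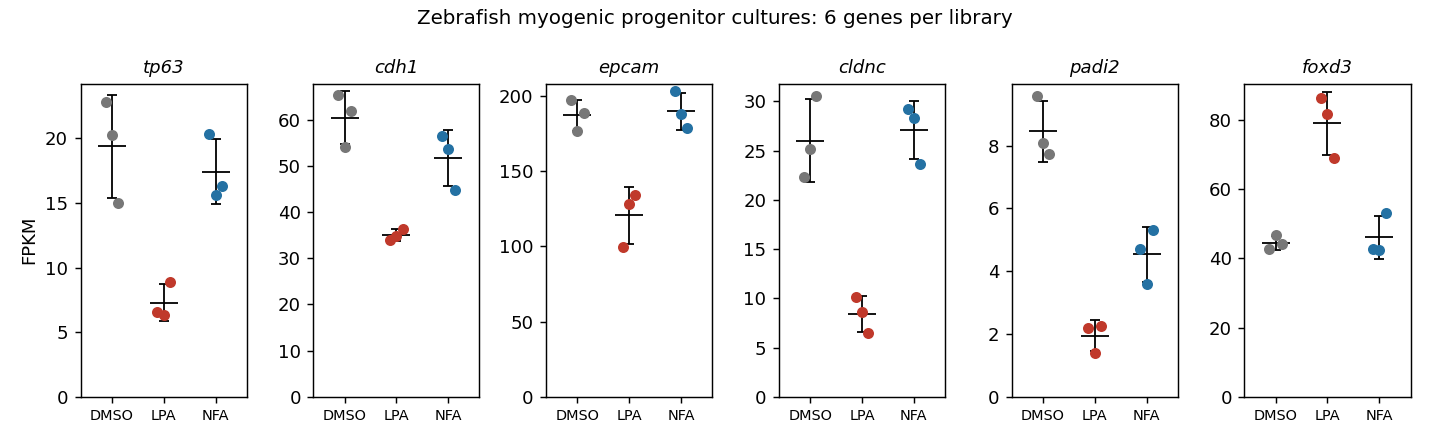
FPKM (vertical axes, from 0) of 6 genes in each zebrafish library treated with DMSO, LPA or NFA; points are libraries, horizontal bars the mean and error bars the SD of 3 libraries. The LPA libraries lie below all DMSO libraries for tp63, cdh1, epcam, cldnc and padi2 and above them for foxd3, whose mean was 44.5 with DMSO and 78.9 with LPA.

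In total 59 genes changed with LPA in zebrafish, 6 higher and 53 lower, and 1342 genes had an unadjusted p under 0.05. The gene padi2, which encodes a peptidylarginine deiminase, fell by 1.69 ± 0.18 on the log2 scale, and vgll4l, which encodes a vestigial-like cofactor, fell by 1.66 ± 0.25. Falls of similar size were seen for the cadherin gene cdh17 (-1.83 ± 0.29), the claudin gene cldn15la (-1.77 ± 0.30), the Crumbs polarity gene crb3b (-1.48 ± 0.24) and tmem176l.4 (-1.80 ± 0.29). Their limma adjusted p lay between 0.00993 for padi2 and 0.0420 for cldn15la. The microRNA genes dre-mir-206-1 and dre-mir-2184 passed the test and were listed at 0 in all 3 LPA and all 3 NFA libraries, so no fold is given. Among the genes that rose, foxd3, which encodes a neural crest transcription factor, went from 44.5 ± 2.06 to 78.9 ± 9.08 FPKM (log2 fold change 0.81 ± 0.12, limma adjusted p = 0.0263). The myeloperoxidase gene mpx rose by 1.14 ± 0.17, the Nogo receptor-like gene rtn4rl2b by 1.01 ± 0.16 and dusp5, a phosphatase gene induced by ERK signalling, by 0.44 ± 0.08. The number of genes depended on single libraries: it was 0 without DMSO replicate 1 or without LPA replicate 1, 1 without DMSO replicate 2, 10 without LPA replicate 2 and 17 without DMSO replicate 3. It was 30 after quantile normalization, with 6 higher and 24 lower, 21 with libraries scaled to the same median and 8 with no filter on low values.

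Other kinds of genes also shifted as lists with LPA in zebrafish, and none of these calls held with an estimated correlation. Genes of the endoplasmic reticulum stress response were higher in 21 of 23 members (median 0.21; camera adjusted p = 3.39e-08; adjusted p = 0.431 with an estimated correlation). Among them were the chaperone gene hspa5 at 0.27 ± 0.07 and dnajc3a at 0.39 ± 0.11. Cholesterol synthesis genes were lower in 20 of 24 members (median -0.22; camera adjusted p = 3.66e-06; adjusted p = 0.431 with an estimated correlation). Members were hmgcs1 at -0.48 ± 0.09 and msmo1 at -0.70 ± 0.15. No cholesterol gene passed over all genes, and 6 were lower when adjusted over the list alone. ERK feedback genes were higher in 16 of 19 members (median 0.16; camera adjusted p = 0.00125; adjusted p = 0.630 with an estimated correlation). Of these, dusp5 passed the test over all genes, dusp2 stood at 0.86 ± 0.21 and etv4 in the other direction at -0.44 ± 0.12. Adjusted over the list alone, 3 ERK feedback genes were higher and 1 was lower. Mitochondrially encoded genes, a list kept as a sign of RNA quality, were higher in 11 of 13 members (median 0.15; camera adjusted p = 0.0112; adjusted p = 0.901 with an estimated correlation). This rested on LPA replicate 2, whose mean over the list relative to DMSO was 0.54, against 0.06 and -0.09 in the other LPA libraries: without it the median was -0.05 (camera adjusted p = 0.875), and without DMSO replicate 3 the list did not pass either (camera adjusted p = 0.118). The endoplasmic reticulum stress, cholesterol and ERK feedback lists passed without any 1 of the 6 libraries. Among neural markers, elavl3 stood at 1.12 ± 0.22 (limma adjusted p = 0.0812), and muscle differentiation genes were lower in 29 of 34 members without passing the list test (median -0.44; camera adjusted p = 0.134). Their mean over the list was -0.66, -1.35 and 0.79 in the LPA libraries and -0.41, 0.71 and -0.29 in the DMSO libraries, so no direction is shown: the median was 0.03 without LPA replicate 2 and 0.00 without DMSO replicate 2, whereas the list was lower and passed without LPA replicate 3 (median -0.90; camera adjusted p = 9.17e-09) or DMSO replicate 1 (median -0.60; camera adjusted p = 0.0121). Without DMSO replicate 1, 9 lists passed.

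NFA changed few genes in zebrafish. There were 2 genes past the threshold, 1 higher and 1 lower, and 436 genes with an unadjusted p under 0.05, 2.74% of those tested and fewer than the 5% expected with no change. These were a 5S ribosomal RNA model listed at 0 in all DMSO libraries and dre-mir-206-1, named here because they are the whole count. The 3 genes with the smallest p in each direction did not pass, apart from that microRNA: mpx at 1.07 ± 0.17, onecut1 at 0.86 ± 0.19 and nefma at 1.2 ± 0.31 on the higher side, and dre-mir-2184, listed at 0 in all NFA libraries, cdh17 at -2.05 ± 0.29 and the chitinase gene chia.6 at -1.49 ± 0.24 on the lower side (limma adjusted p between 0.113 and 1.00). With any 1 of the DMSO libraries left out, or NFA replicate 1 or 2, no gene passed, and without NFA replicate 3 there was 1.

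By the list test 8 lists shifted with NFA in zebrafish, and none did with an estimated correlation, where the adjusted p was 0.493 or higher. Cholesterol synthesis genes were lower in 18 of 24 members (median -0.13; camera adjusted p = 0.00217), with dhcr7 at -0.34 ± 0.10 and hmgcs1 at -0.24 ± 0.09. Genes of the integrated stress response were lower in 29 of 37 (median -0.08; camera adjusted p = 0.0135), with chac1 at -0.30 ± 0.11 and sesn2 at -0.27 ± 0.12. Heat shock genes were lower in 24 of 28 (camera adjusted p = 0.0205), immediate-early genes in 22 of 31 (camera adjusted p = 0.0243), p53 targets in 9 of 13 (camera adjusted p = 0.0336) and TGF-beta and BMP targets in 14 of 19 (camera adjusted p = 0.0427). Examples were hspb1 at -0.44 ± 0.24, fosab at -0.37 ± 0.12, cdkn1a at -0.38 ± 0.13, pmaip1 at -0.39 ± 0.12 and id3 at -0.23 ± 0.10. Collagen and matrix genes were higher in 16 of 20 (median 0.18; camera adjusted p = 0.0205), with dcn at 0.25 ± 0.11 and col1a1b at 0.41 ± 0.23, and blood and immune cell markers in 5 of 6, led by mpx (camera adjusted p = 0.0205). The only one of these genes that passed when adjusted over its list alone was mpx. The epithelial list did not pass with NFA (median -0.13; camera adjusted p = 0.194). The cholesterol list passed without any 1 of the 6 DMSO and NFA libraries. The other 7 each did not pass without at least 1 of them: the integrated stress response list without DMSO replicate 1, the heat shock list without DMSO replicate 1 or NFA replicate 3, the immediate-early list without DMSO replicate 1 or 3 or NFA replicate 2 or 3, the p53 list without DMSO replicate 1 or NFA replicate 1 or 3, the TGF-beta and BMP list without DMSO replicate 1 or 3 or NFA replicate 1 or 2, the collagen and matrix list without DMSO replicate 1 or 2 or NFA replicate 1 or 3 and the blood and immune list without DMSO replicate 2 or 3 or NFA replicate 2 (camera adjusted p up to 0.672 for these lists). The count of lists was 3 without DMSO replicate 1, 5 without DMSO replicate 3 and 4 after quantile normalization.

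Compared directly in zebrafish, LPA and NFA differed in 37 genes, 5 higher and 32 lower with LPA, and in 1113 genes at an unadjusted p under 0.05. With LPA replicate 3 and NFA replicate 3 exchanged between the groups the count was 439 rather than 37, so these libraries also differ along something other than the labelled treatment. Lower with LPA were vgll4l (-1.79 ± 0.25), cldnc (-1.59 ± 0.17), cldn1 (-1.45 ± 0.20), s100v1 (-1.40 ± 0.16) and the serine protease gene tmprss2 (-1.27 ± 0.19), with limma adjusted p between 0.0200 and 0.0391. Higher with LPA were foxd3 (0.77 ± 0.12) and dusp5 (0.55 ± 0.08), while rtn4rl2b (0.92 ± 0.16), acp5a (1.05 ± 0.19) and isl1 (1.2 ± 0.25) did not pass. All 12 epithelial markers were lower with LPA than with NFA (median -0.69; camera adjusted p = 8.61e-13; adjusted p = 0.0325 with an estimated correlation, between 0.0234 and 0.179 over 13 alternatives and under 0.05 in 5 of them), 1 of them past the test over all genes, tp63 at -1.16 ± 0.18, and 9 when adjusted over the list alone. With an estimated correlation the list did not pass with a replicate block, with libraries scaled to the same median, or without DMSO replicate 2, any 1 of the LPA replicates, NFA replicate 2 or NFA replicate 3. Of its 12 members 11 were lower without LPA replicate 1, LPA replicate 3 or NFA replicate 1, and 10 without NFA replicate 2. Endoplasmic reticulum stress genes were higher with LPA in 20 of 23 (camera adjusted p = 2.72e-10) and ERK feedback genes in 17 of 19 (camera adjusted p = 4.79e-06), but neither passed with an estimated correlation (adjusted p = 0.416 for both). Also higher by camera, and not passing with an estimated correlation either (adjusted p = 0.715 for each), were hypoxia and glycolysis genes in 33 of 44 (camera adjusted p = 0.000260), mitochondrially encoded genes in 13 of 13 (camera adjusted p = 0.000260) and immediate-early genes in 24 of 31 (camera adjusted p = 0.0120). Cholesterol genes were lower in 17 of 24 (camera adjusted p = 0.0474; adjusted p = 0.715 with an estimated correlation). The mitochondrially encoded list, a sign of RNA quality, again rested on LPA replicate 2, without which its median went from 0.20 to 0.02 (camera adjusted p = 0.478). The immediate-early list did not pass without LPA replicate 3 or NFA replicate 3, nor the cholesterol list without LPA replicate 2 or 3 or NFA replicate 1 or 3 (camera adjusted p up to 0.336 and 0.278). Examples were hspa5 at 0.34 ± 0.07, spry4 at 0.50 ± 0.14, slc2a3b at 0.34 ± 0.12, mt-co1 at 0.46 ± 0.13, fosl1a at 0.46 ± 0.11 and ldlrb at -0.54 ± 0.14. Adjusted over the list alone, 5 endoplasmic reticulum stress genes and 5 ERK feedback genes were higher. Without LPA replicate 1 or NFA replicate 2 there were 11 lists. The count of genes was 0 without LPA replicate 2, without NFA replicate 2 or with only the 6 libraries of both groups. It was 1 without LPA replicate 1 or NFA replicate 1, 10 without NFA replicate 3 and 21 without LPA replicate 3, and after quantile normalization it was 7, with 3 higher and 4 lower.

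**Figure D2:**
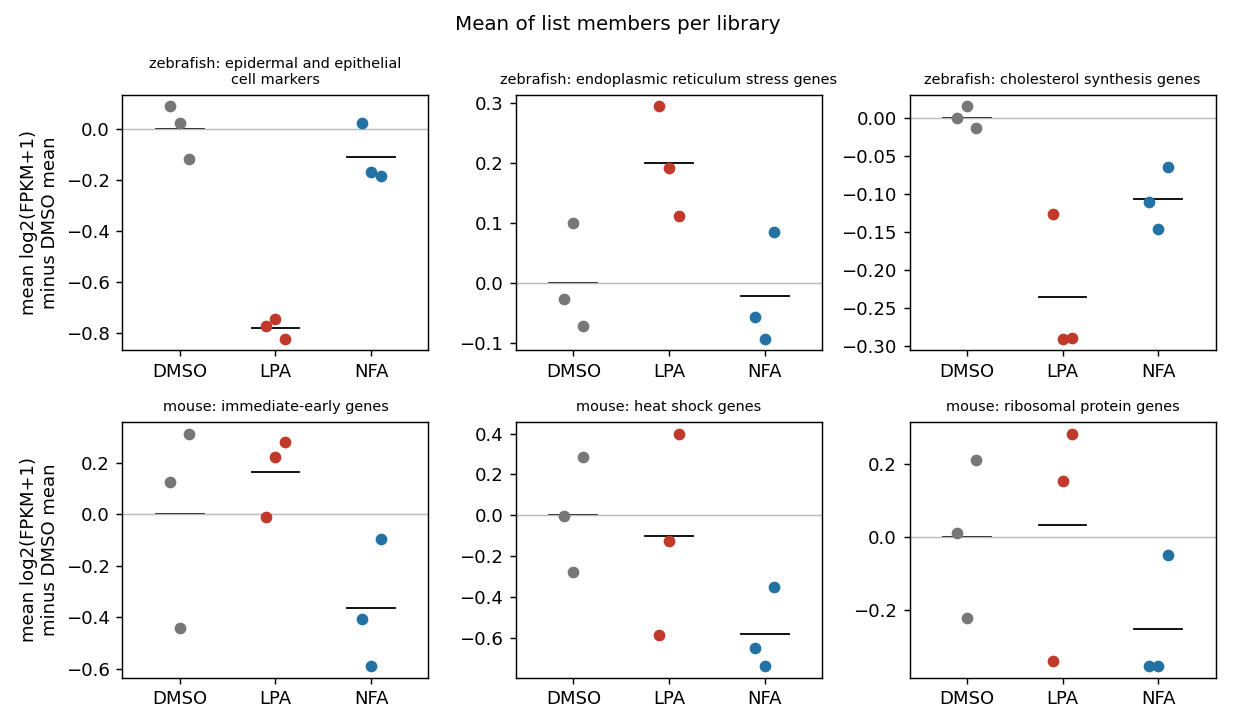
Mean of log2(FPKM + 1) over the members of a gene list in each library, minus the DMSO mean (vertical axes in log2 units), for 3 lists in zebrafish and 3 in mouse; points are libraries and bars the means of 3 libraries. The zebrafish LPA libraries lie between -0.82 and -0.75 for the epithelial list, apart from all DMSO and NFA libraries, whereas the mouse libraries of one group spread widely.

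In the mouse muscle stem cells, the protein-coding gene that changed with LPA was Tlr13, which encodes an endosomal receptor for bacterial ribosomal RNA. Tlr13 (ENSMUSG00000033777; GRCm38 chromosome X, 106143204 to 106160493, plus strand) fell from 14.5 ± 5.54 FPKM with DMSO to 0.516 ± 0.53 with LPA, a log2 fold change of -3.35 ± 0.38 (limma adjusted p = 0.0272). It did not pass without DMSO replicate 1 or 2, or without LPA replicate 1 or 2. The other 3 of the 4 changed genes were short non-coding RNA models. Of the genes next in order, Postn, which encodes the matrix protein periostin (ENSMUSG00000027750; chromosome 3, 54361109 to 54391037, plus strand), did not pass. It had 6.16 ± 3.85 FPKM with DMSO and 41.4 ± 17.0 with LPA and was higher in all 3 LPA libraries than in the 3 DMSO libraries (log2 fold change 2.65 ± 0.53, limma adjusted p = 0.606). Groups without overlap were seen in 7.93% of tested mouse genes for LPA against DMSO, where 10% would be so by chance. The lack of overlap alone is therefore no evidence of a change in Postn. Gmip stood at 1.16 ± 0.26 and the pseudogene Mrps36-ps2 at 1.82 ± 0.41 on the higher side, and Tmem81 at -1.50 ± 0.33, Olfr1313 at -1.44 ± 0.34 and Vmn1r12, listed at 0 in all LPA libraries, on the lower side, none of them past the threshold. At an unadjusted p under 0.05 there were 983 genes, 4.06% of those tested and fewer than the 5% expected with no change, and the count of genes past the threshold was 0 without DMSO replicate 1, 9 without DMSO replicate 3 and 7 without LPA replicate 3. No list shifted with LPA in mouse. Muscle differentiation genes were higher in 22 of 28 (median 0.28; camera adjusted p = 0.0654), with Acta1 at 0.80 ± 0.32. Immediate-early genes were higher in 23 of 26 (median 0.20; camera adjusted p = 0.0913), with Nr4a1 at 0.59 ± 0.29. Mitochondrially encoded genes were lower in 13 of 13 (median -0.25; camera adjusted p = 0.0654), with mt-Nd4 at -0.30 ± 0.24. Between 1 and 5 lists passed when a library was left out.

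With NFA, Tlr13 was again the protein-coding gene that changed in mouse, at 0.342 ± 0.19 FPKM (log2 fold change -3.48 ± 0.38, limma adjusted p = 0.0289), measured against the same 3 DMSO libraries. This call was lost without any single one of the 6 DMSO and NFA libraries. The other 4 of the 5 changed genes were short RNA models that were listed at 0 in all DMSO libraries, and 1606 genes had an unadjusted p under 0.05. Without DMSO replicate 1, NFA replicate 2 or NFA replicate 3, no gene passed, and 2 did without DMSO replicate 3 or NFA replicate 1. Genes next in order did not pass: Olfr267 at 2.18 ± 0.36, Snora26 and Ighv11-1, both listed at 0 in all DMSO libraries, C78339 at -1.37 ± 0.28, Vps51 at -1.69 ± 0.35 and Spopl at -1.15 ± 0.26.

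By the list test 12 lists were lower and 1 was higher with NFA in mouse, although no member of any of them passed over all genes or when adjusted over its list alone, and none of the calls held with an estimated correlation (adjusted p = 0.651 with an estimated correlation for each). Heat shock genes were lower in 17 of 17 (median -0.63; camera adjusted p = 3.42e-07), with Dnaja1 at -0.94 ± 0.32 and Hspb8 at -0.89 ± 0.29, and ribosomal protein genes in 64 of 65 (median -0.25; camera adjusted p = 1.42e-06), with Rpl35 at -0.81 ± 0.26. Endoplasmic reticulum stress genes were lower in 17 of 19 (camera adjusted p = 8.68e-06), with Dnajb9 at -0.74 ± 0.27 and Hspa5 at -0.62 ± 0.31, and immediate-early genes in 24 of 26 (camera adjusted p = 2.12e-05), with Maff at -0.70 ± 0.29 and Klf4 at -0.45 ± 0.24. Ribosome biogenesis genes were lower in 26 of 27 (camera adjusted p = 0.000604; Nat10 at -0.71 ± 0.25). Also lower were integrated stress response genes in 28 of 32 (0.00125; Atf3 at -0.94 ± 0.36), ERK feedback genes in 15 of 17 (0.00150; Dusp4 at -0.998 ± 0.304 and, in the other direction, Lif at 1.18 ± 0.40) and housekeeping genes in 11 of 13 (0.00305; Hprt at -0.68 ± 0.31). Muscle stem cell quiescence genes were lower in 24 of 31 (0.00613; Gas1 at -0.94 ± 0.28 and Megf10 at -0.65 ± 0.24) and mitochondrially encoded genes in 13 of 13 (0.00876; mt-Nd6 at -0.52 ± 0.22). The p53 targets were lower in 12 of 16 (0.0140; Mdm2 at -0.58 ± 0.24) and TGF-beta and BMP targets in 13 of 17 (0.0194; Skil at -0.61 ± 0.28). Endothelial cell markers were higher in 8 of 10 (camera adjusted p = 0.0490; Tie1 at 0.70 ± 0.36). Housekeeping and ribosomal protein genes were kept as signs of RNA quality, and they moved with the pathway lists. Among the 3775 genes with a mean FPKM of at least 20, the median log2 fold change with NFA was -0.29. The heat shock, ribosomal protein, endoplasmic reticulum stress and immediate-early lists passed without any 1 of the 6 DMSO and NFA libraries. Without DMSO replicate 3 the other lists did not pass, apart from the mitochondrially encoded one, which did not pass without DMSO replicate 1 or NFA replicate 3. The quiescence and p53 lists also did not pass without DMSO replicate 1 or NFA replicate 2, the TGF-beta and BMP list without NFA replicate 1 or 2 and the endothelial list without DMSO replicate 1 or any 1 of the NFA replicates (camera adjusted p up to 0.620 for these lists). Tested among these genes 1 list passed, after quantile normalization 2, without DMSO replicate 2 there were 20 and without DMSO replicate 3 there were 5.

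LPA and NFA differed in mouse in 10 genes, 2 higher and 8 lower with LPA, all of them short RNA models, and in 1556 genes at an unadjusted p under 0.05. Next in order and not past the threshold were Postn (2.67 ± 0.53), Tnnt1 (1.51 ± 0.33) and Hoxb7, listed at 0 in all NFA libraries, on the higher side, and Olfr1136 (-2.15 ± 0.36), the pseudogene Rps16-ps3 (-2.10 ± 0.35) and Bcl9 (-1.67 ± 0.34) on the lower side. By the list test 14 lists were higher with LPA, and none of these calls held with an estimated correlation (adjusted p = 0.580 for each). Among them were immediate-early genes in 24 of 26 (median 0.58; camera adjusted p = 9.19e-10), with Nr4a1 at 1.02 ± 0.29 and Maff at 0.90 ± 0.28. Also higher were ribosomal protein genes in 62 of 65 (camera adjusted p = 1.04e-08), with Rpl22 at 0.62 ± 0.22, and heat shock genes in 17 of 17 (camera adjusted p = 1.27e-05), with Hspb8 at 1.04 ± 0.29. Quiescence genes were higher in 28 of 31 (camera adjusted p = 0.000110), with Col5a3 at 0.69 ± 0.23, and SRF and MRTF targets in 22 of 25 (camera adjusted p = 0.00220), with Tln1 at 0.69 ± 0.28. These 5 lists passed without any 1 of the 6 libraries. Housekeeping genes, which like ribosomal protein genes were kept as a sign of RNA quality, were higher in 12 of 13 (median 0.35; camera adjusted p = 0.00410) and did not pass without LPA replicate 3 (camera adjusted p = 0.0899), so these quality lists moved with the pathway lists. After quantile normalization 5 lists passed. The count of genes was 0 without NFA replicate 2, 2 without LPA replicate 3, 5 without NFA replicate 1 and 17 without NFA replicate 3.

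Genes that encode receptors for lysophosphatidic acid and the cyclooxygenases were read out in both species, and none passed the test. In mouse, Lpar1 was the most abundant receptor gene, at 35.4 ± 6.10 FPKM with DMSO, 42.6 ± 9.94 with LPA and 24.1 ± 7.41 with NFA. Lpar3, Lpar4 and Lpar6 had 1.16 ± 1.18, 4 ± 1.95 and 4.14 ± 2.07 FPKM with DMSO, 0.589 ± 0.26, 5.27 ± 1.73 and 3.48 ± 1.87 with LPA, and 3.48 ± 1.00, 5.43 ± 1.79 and 1.84 ± 1.08 with NFA. With NFA the log2 fold change was 1.16 ± 0.42 for Lpar3 and -0.85 ± 0.44 for Lpar6 (limma adjusted p = 0.721 and 0.744). In the DMSO libraries Lpar2 and Lpar5, at 0.264 ± 0.20 and 0.177 ± 0.31, were not tested. Ptgs1 had 1.32 ± 0.63 FPKM with DMSO and 3.30 ± 0.86 with NFA, and Ptgs2 had 2.63 ± 2.86 and 1.55 ± 0.95. In zebrafish, lpar1 had 31.7 ± 5.53 FPKM with DMSO, 32.7 ± 2.85 with LPA and 31.6 ± 4.96 with NFA. With LPA, lpar2b stood at -0.62 ± 0.17, lpar3 at -0.50 ± 0.19, lpar2a at -0.22 ± 0.15, lpar6a at -0.09 ± 0.14 and lpar6b at -0.36 ± 0.23. The cyclooxygenase gene ptgs2a had 15.3 ± 5.48 FPKM with DMSO, 3.97 ± 1.49 with LPA and 12.2 ± 5.37 with NFA (LPA against DMSO -1.71 ± 0.36, limma adjusted p = 0.106), ptgs2b stood at -0.33 ± 0.18 and ptgs1 at -0.53 ± 0.25 with LPA. With NFA the log2 fold changes of the tested zebrafish receptor and cyclooxygenase genes lay between -0.47 for ptgs1 and 0.17 for lpar3. The genes lpar4, lpar5a and lpar5b were below the filter.

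The responses to both compounds were compared across genes. The correlation of the LPA and NFA log2 fold changes was 0.443 in mouse (Spearman 0.406) and 0.474 in zebrafish (Spearman 0.456), where unchanged groups against the same DMSO libraries gave a simulated mean of 0.5 (range 0.475 to 0.523) and 0.502 (range 0.467 to 0.546) over 100 simulations. The mouse value lay below its simulated range and the zebrafish value inside. The simulated genes were independent, unlike real ones, so the simulated range may be too narrow. The SD of the correlation over fits that left out 1 library each was 0.084 in mouse and 0.089 in zebrafish. Leaving out a library also changes the correlation that unchanged groups would give, so this SD does not measure the spread. Whether the mouse value departs from unchanged groups is therefore not decided. The covariance was 0.129 against a simulated 0.113 in mouse and 0.0323 against 0.0258 in zebrafish. The genes past the threshold with both compounds were Tlr13 in mouse and dre-mir-206-1 in zebrafish, both lower, and part of this overlap may come from the shared DMSO libraries, which are too few to split. The microRNA gene had just 2.44 ± 0.59 FPKM with DMSO and was listed at 0 in all other zebrafish libraries. FPKM of such short genes are unstable. Without short-RNA names 0 zebrafish genes passed with NFA, so a shared response is not shown by this gene. Passing with LPA alone is no difference between the compounds. In zebrafish mpx stood at 1.14 with LPA and 1.07 with NFA, and cdh17 at -1.83 and -2.05. The microRNA gene dre-mir-2184 was listed at 0 in all LPA and NFA libraries. All of these passed with LPA only. Differences between the compounds rest on the direct comparison above. Between the species, 8387 genes could be matched by symbol, and the correlation of their log2 fold changes was -0.02 for LPA (Spearman -0.02) and 0.03 for NFA (Spearman 0.05). The mouse log2 fold changes had a median standard error of 0.388, and such noise weakens a correlation. The media also differed, with horse serum and bFGF in mouse only. These values therefore do not show that the species responded differently. Of the matched genes, 23 were lower with LPA in zebrafish. By limma 0 matched genes were changed by LPA in mouse, and at an unadjusted p under 0.05 in mouse 1 of the 23 was lower (79 of all matched genes were). The median mouse log2 fold change of those 23 was 0.05. With NFA 0 matched genes were changed in either species by limma, and 417 matched genes were lower in mouse at an unadjusted p under 0.05. With 0 changed mouse genes among the matched ones for either compound, no overlap of changed genes between the species could arise. In a test of 74 differences between the species, list by list and compound by compound, the smallest exact permutation p was 0.02 and no adjusted p was under 0.925. The smallest p these libraries can give is 0.005, which for a single list is an adjusted p of 0.37, and 8 lists would have to reach it to pass, so this test does not show whether lists responded alike. The epithelial list, with 3 tested mouse members, was not among the tests.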

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

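The alternatives that tested protein-coding genes, used a residual component, tested lists among genes of mean FPKM of at least 20 or after quantile normalization, left out libraries for lists, or left out NFA replicate 3 for LPA against DMSO were chosen after seeing the data. Causes were not tested except where fewer libraries or genes were used. For named genes, 1793 of 2063 alternatives kept direction and side of the threshold, 234 no longer passed, 16 newly passed and 20 changed sign, all of genes that did not pass. Many named genes did not pass to begin with and had no call to lose. The 234 lost calls all concern genes that had passed, so 1793 of 2063 is not the share of calls that held. Scaling to the same median moved the median of all mouse genes with NFA to -0.12.

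Replicate numbers did not clearly pair the libraries. In mouse, residuals of equal numbers correlated between -0.07 and 0.13, against -0.16 to 0.13 for unequal numbers. In zebrafish these ranges were -0.25 to 0.09 and -0.17 to 0.24. Among libraries of other groups, 5 of 9 mouse libraries and 1 of 9 zebrafish libraries correlated best with their own number. Pairing in mouse is therefore not decided. With a replicate block 0 genes passed in each of the 6 comparisons, and for mouse LPA against DMSO 3 lists did.

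For mouse LPA against DMSO, 8 genes passed with a pseudocount of 0.1, 1 with FPKM of at least 5, 10 with only 6 libraries, 1 among protein-coding genes and 0 with the residual component. Lists numbered 1 among genes of mean FPKM of at least 20 and 3 after quantile normalization. Leaving out libraries gave 0 to 9 genes and 1 to 5 lists. For mouse NFA, 0 genes passed with a pseudocount of 0.1, 0 with FPKM of at least 5, 1 among protein-coding genes and 0 with the residual component. Lists numbered 0 with an estimated correlation, 0 with fry, 1 among genes of mean FPKM of at least 20 and 2 after quantile normalization, and leaving out libraries gave 0 to 5 genes and 5 to 20 lists. For mouse LPA against NFA, 3 genes passed with FPKM of at least 5 and 0 among protein-coding genes. Lists numbered 0 with an estimated correlation, 0 with fry, 1 among genes of mean FPKM of at least 20 and 5 after quantile normalization, and leaving out libraries gave 0 to 17 genes and 11 to 17 lists.

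For zebrafish LPA against DMSO, 8 genes passed without a filter, 30 after quantile normalization (29 of them shared with the 59), 21 with the same median (all shared), 25 without the trend, 35 with only 6 libraries and 168 with the residual component. Lists numbered 1 with an estimated correlation and 2 with fry, and leaving out libraries gave 0 to 58 genes and 4 to 9 lists. For zebrafish NFA, 0 genes passed with a pseudocount of 0.1, with FPKM of at least 5, with the same median, with only 6 libraries, without short-RNA names or with the residual component, 1 after quantile normalization and 6 with array weights. Lists numbered 0 with an estimated correlation, 2 with fry and 4 after quantile normalization, and leaving out libraries gave 0 to 1 genes and 3 to 8 lists. For zebrafish LPA against NFA, 2 genes passed without a filter, 7 after quantile normalization, 5 with the same median, 8 without the trend, 79 with array weights, 0 with only 6 libraries and 90 with the residual component. Lists numbered 1 with an estimated correlation and 1 with fry, and leaving out libraries gave 0 to 21 genes and 6 to 11 lists. The correlation of mouse and zebrafish NFA responses was 0.0212 after quantile normalization.

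Changes of sign concerned always-given genes that did not pass. In mouse, leaving out libraries moved the log2 fold change with LPA between -0.57 and 0.0885 for Lpar3, -0.52 and 0.11 for Lpar6 and -0.45 and 0.54 for Ptgs2, and with NFA between -0.67 and 0.31 for Ptgs2. In zebrafish it moved lpar1 with LPA between -0.0398 and 0.19, and with NFA ptgs2a between -0.58 and 0.0482, ptgs2b between -0.22 and 0.19, lpar1 between -0.10 and 0.13, lpar2b between -0.0789 and 0.0735 and lpar6a between -0.19 and 0.0748. With NFA, ptgs2b stood at 0.00547 after quantile normalization and 0.14 with array weights, and lpar1 at 0.0307 after quantile normalization, 0.000854 with the same median and 0.11 with array weights.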

Other observations

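The test of the share of epithelial cells, the count of genes at 0 in whole groups and the repeats of the epithelial list under other settings were chosen only after the result was seen, as was the fold that the test of 1 scale factor per library had to keep; that test itself and the test of gene length in other splits were added after seeing the data but before their own results. The zebrafish epithelial list was lower with LPA in each library: the mean over its members, relative to DMSO, was -0.78, -0.75 and -0.82 in the LPA libraries, 0.09, 0.03 and -0.12 in the DMSO libraries and 0.03, -0.17 and -0.18 in the NFA libraries. Under 13 alternatives its median log2 fold change against DMSO stayed between -0.87 and -0.66 and the camera adjusted p was at most 1.07e-10, although with an estimated correlation only 7 of the 13 gave an adjusted p under 0.05 (range 0.0205 to 0.145). The replicate block and leaving out an NFA library cannot change this median, so those alternatives say nothing about its stability.

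The first pattern weighed is this fall of epithelial genes. The fall did not follow the largest component of the libraries. With the first component of all other genes outside the list and the LPA calls as a covariate, the list mean was -0.77 ± 0.10 (SE) against -0.78 ± 0.08 without it. The first component of all tested genes was 32.9, 20.7 and -8.15 in the LPA libraries and -20.0, -7.09 and -6.81 in the DMSO libraries. A component that splits the LPA libraries can hardly absorb a fall of similar size in all of them. The test therefore cannot exclude another component or a batch that follows the treatment. A smaller share of epithelial cells in the LPA cultures stays open. Log2 fold changes of members ran from -0.16 to -1.48, and 5 of the 12 lay more than 2 SE from their weighted mean of -0.56. Fewer epithelial cells would lower members by a common factor. Other cells may express some members, however, and FPKM + 1 understates the change of low ones, so unequal falls do not decide. Fewer epithelial cells would also raise the markers of other cell types, by an amount that depends on the epithelial share. That share is unknown, so the rise could be too small to see. Blood and immune cell markers were higher with LPA in 5 of 6 (median 0.25; camera adjusted p = 0.0759; fry adjusted p = 0.0157), with means of 0.40, 0.21 and 0.46 in the LPA libraries and 0.10, -0.02 and -0.08 in the DMSO libraries, and neural markers in 8 of 11 (median 0.22; camera adjusted p = 0.0759; fry adjusted p = 0.557). Medians were 0.37 for smooth muscle and pericyte markers and 0.14 for neural crest and pigment cell markers, but -0.17 for fibro-adipogenic and tendon markers (8 of 11 lower), -0.12 for endothelial markers (6 of 11 lower), -0.02 for Schwann and glial markers and -0.01 for blastoderm and germ layer markers, so other cell types did not move in 1 direction; by camera none of these 8 lists passed. Blood and immune markers were also higher with NFA in 5 of 6, where the epithelial list did not pass, so this does not decide either. A lower level of these transcripts within cells after 2 h of LPA is another open hypothesis, and these data cannot tell it apart from a change in cell share.

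The second pattern is that 10 of the 11 genes called in any mouse comparison had exons of under 200 bases in total, against 7.44% of tested genes. A candidate explanation is the instability of FPKM for genes shorter than a sequenced fragment, which would make short genes pass in any grouping of the libraries. In the 27 splits of 6 mouse libraries that do not follow the treatments, 214 genes passed that were not among the 11, and of the 205 with a known length and distinct values 97.6% were short, as this explanation needs. The 11 genes are not independent, since Gm23889 and Gm22814 had identical values. Another explanation is that the authors' tool set whole groups to 0, and it stays open: of the 10 short genes 4 were at 0 in all libraries of 1 group and 6 in those of 2 groups. Counting genes at 0 in just 3 libraries or above 0 in just 3, 0 of the 3 groups had more than any other set of 3 libraries, at 30 for DMSO, 52 for LPA and 46 for NFA against a median of 35 and up to 57 for other sets. Genes at 0 in just 3 libraries numbered 43 for LPA against a median of 16 and up to 50 for other sets. Genes above 0 in just 3 libraries numbered 37 for NFA against a median of 16 and up to 40. A few genes set to 0 therefore cannot be told apart from chance zeros. The mouse LPA libraries also appeared shallower than the others, and whether depth accounts for these zeros was not tested. No biological explanation was tested.

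The third pattern is that expressed-gene lists were lower with NFA in mouse. Reads from background diluting expressed genes may account for part of it: tested among genes with a mean FPKM of at least 20, where 22 lists rather than 37 had enough members but all 12 lower ones did, 1 list was still lower. That was the heat shock list (camera adjusted p = 0.0205). The falls themselves stayed about as large, with medians of the 12 lists between -0.63 and -0.21 among all members and between -0.61 and -0.25 among expressed ones. The calls ended because the genes they were compared with were lower too, by a median of -0.29, and because some lists had fewer members, so lost calls are weak support. After quantile normalization 2 lists were lower, and the medians of the 12 lists lay between -0.40 and 0.06, but this also removes a real difference that expressed genes share, so it does not decide about scaling. A wrong scale factor of each library stays open too. With 1 factor per library that gives genes with a mean FPKM of at least 20 the same median, 7 lists were still lower, but their medians shrank from between -0.63 and -0.33 to between -0.38 (heat shock genes) and -0.08 (ribosome biogenesis genes), and they passed in part because the median of all genes rose to 0.18, so a bound on the number of lists alone was not enough. A real lower level of expressed genes with NFA stays open, as untested. The mean FPKM of 1817 olfactory, vomeronasal and taste receptor genes was 1.61, 2.12 and 1.2 in the DMSO libraries and 1.95, 2.16 and 1.57 in the NFA libraries. It was 1.74, 1.28 and 1.33 in the LPA libraries, so the groups overlapped. Library by library, however, more of this background went with lower housekeeping genes. The mean of that list relative to DMSO was -0.02, -0.24 and 0.26 in the DMSO libraries. It was -0.34, 0.03 and 0.20 in the LPA libraries and -0.51, -0.38 and -0.17 in the NFA libraries. Dilution by background stays open, and this relation was not tested.

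With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real counts of genes and the highest of the other splits were 4 and 13 for LPA, 5 and 18 for NFA and 10 and 13 for LPA against NFA in mouse, with 10, 8 and 3 splits giving as many, the real one included. In zebrafish they were 59 and 8, 2 and 5, and 37 and 439, with 1, 6 and 2 splits giving as many. For lists they were 0 and 16, 13 and 16, and 14 and 16 in mouse, with 10, 4 and 2 splits, and 5 and 9, 8 and 6, and 7 and 8 in zebrafish, with 6, 1 and 4 splits. The split with 439 genes set LPA replicates 1 and 2 with NFA replicate 3 against the others, which points to a structure of these libraries apart from the treatment labels. It is the split that exchanges LPA replicate 3 and NFA replicate 3, and an exchange of libraries or an unlabelled batch stays open. On the epithelial list LPA replicate 3 (-0.82) lay with the LPA libraries and NFA replicate 3 (-0.18) with the NFA libraries, which speaks against an exchange of these 2 but does not exclude it. The first component of all tested genes went the other way. On it LPA replicate 3 (-8.15) lay with NFA replicates 1 and 2 (-7.39 and -25.7). NFA replicate 3 (21.6) lay with LPA replicates 1 and 2 (32.9 and 20.7).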
